A study of Mus musculus with 9 samples.

How the data were processed

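RNA of sorted spleen Treg cells was measured by sequencing in 9 mouse libraries, 3 each of WT, Usp21 KO and Usp22/Usp21 dKO, which the sample titles number as separate biological samples. The deposited table holds raw counts per Ensembl gene, 1 column per library, with no pooling of replicates and no filter on low counts, as its values show. Per the submitters' processing notes, cutadapt 1.13, STAR (no version given), HTSeq 0.6.1p1 and DESeq2 1.14.1 were used with genome build mm10. The order of steps, the strand option and the annotation release are not recorded, so reads from genes that overlap on opposite strands may not be separable. The table held 54232 genes and 0 summary lines, of which 25440 were at 0 in all libraries. Of the gene IDs, 54079 were found in GENCODE M21, which served for coordinates, and 153 were not. Symbols came from the table for 23956 genes and from GENCODE for 30167, and 109 kept their ID. No pair of libraries was a duplicate of another, since the lowest chi-square per degree of freedom between any pair was 5.08.

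Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 3 groups (14994 genes), and library sizes were scaled by TMM factors, which lay between 0.964 and 0.991 in WT and Usp21 KO and between 1.04 and 1.05 in dKO. One quasi-likelihood fit with robust dispersions (glmQLFit, glmQLFTest) over all 9 libraries with group as the sole term gave the 3 comparisons, Usp21 KO against WT, dKO against WT and dKO against Usp21 KO. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The common biological coefficient of variation was 0.174. CPM values were computed from the TMM-scaled library sizes. The replicate number was not used as a block, since the labels mark separate biological samples and those that share a number did not deviate together across all 3 groups.

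Total counts ran from 18067377 to 40334577 per library, and with 3 libraries per group the spread between libraries limited precision. The procedure was tested on simulated data built from the real genes' means and library sizes in 5 sets. For dKO against WT, with 14994 genes tested, it recovered 47.8% of genes changed 1.5-fold, 70.5% of those changed 2-fold and 91.5% of those changed 4-fold, and passed 0.06% of unchanged genes. For Usp21 KO against WT, simulated without any change, it passed 0.01% of genes. The list test called 5 of 5 lists of 30 genes shifted by a log2 change of 0.4 and 0 of 100 unchanged lists. The simulated genes were drawn independently and the unchanged lists held random genes. The 0 of 100 therefore does not cover lists whose members vary together, such as the cell cycle list (estimated correlation 0.73 in Usp21 KO against WT).

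Before the data were examined, the comparisons, 29 gene lists and a rule for named genes were fixed. The lists covered Treg identity, effector Treg, naive T cell and T helper genes, metabolism (oxidative phosphorylation, mitochondrially encoded genes, glycolysis, hypoxia, amino acid response, cholesterol synthesis), cell cycle, signalling (type I interferon, NF-kB, TGF-beta, IL-2 and STAT5), the SAGA complex, other deubiquitinases, stress (heat shock, immediate early genes, p53 and apoptosis), homing receptors, cytosolic ribosomal proteins, markers of B, plasma, myeloid, CD8 T and NK, erythroid and conventional CD4 T cells, and sex-linked genes. The 27 lists with at least 5 measured members were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and beside it with an estimated correlation and with fry. The setting with an estimated correlation raised p even where the estimate lay below the preset. For a list with an estimate near or below the preset, a call lost under it is therefore no evidence that correlation between genes produced the call. Estimates were far above the preset for other lists, such as cell cycle (0.732), effector Treg (0.646) and ribosomal proteins (0.492) in Usp21 KO against WT. For such lists correlation may account for part of the loss, and p-values at the preset may be far too small. Named genes were Usp21, Usp22 and Foxp3; the 10 with the largest rise and the 10 with the largest fall among genes that passed, did not overlap between groups and had a mean log2 CPM of at least 1, without predicted models, immunoglobulin and T cell receptor segments and sex-linked genes; up to 4 members per list that passed, or up to 2 with the smallest p where none did; and the 5 with the smallest p where fewer than 5 passed. Per-library values of Itgae, Pianp, Stab1, Dscam and Nrn1, the genes Il2ra, Ctla4, Cd5, Lyz2, S100a8, Igkc, Hbb-bs, Nkg7, Cd74, Cst3, Ccl5 and Abhd14a and the Gimap and Mcm genes were chosen after their values were seen.

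Alternatives fixed in advance were size factors by the median ratio, library totals, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma voom, the 6 libraries of a comparison alone, a replicate block, a 1.5-fold threshold (glmTreat), leaving out each library in turn, and an adjusted p of 0.10 for shared genes. Added after the data were seen were a fit without the 3 libraries that scored highest in immediate early genes within their group, and fits with the immediate early score or the score of other cell types as a covariate. Every dKO library scored higher for other cell types than any WT or Usp21 KO library. As a covariate that score therefore takes up part of the genotype difference, and calls lost with it do not show their cause. A list score is the mean log2 CPM of the members, centred on the mean of the 9 libraries. The scores of the B cell, myeloid, CD8 T and NK, and erythroid lists, and the 6 differences between them, were compared between dKO and WT with limma, adjusted over the 4 lists or the 6 differences. Simulations of unchanged groups against shared libraries were drawn 20 times. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.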

Results

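RNA was sequenced from spleen regulatory T (Treg) cells of mice, sorted by a fluorescent reporter of Foxp3, the transcription factor that defines this cell type. The 9 libraries comprised 3 from wild-type (WT) mice, 3 labelled as knockout of the deubiquitinase Usp21 (Usp21 KO) and 3 labelled as double knockout of Usp22 and Usp21 (dKO). The labels give neither the deleted exons nor the cells in which the deletions act. Usp22 is the deubiquitinase subunit of the SAGA transcriptional coactivator complex. The design held no group with loss of Usp22 alone, so its effect was measured only beside loss of Usp21. The records name neither the strain nor litters of the mice, so differences between the lines apart from the targeted genes cannot be told from effects of the losses. The table gave counts for 54232 genes, of which 28792 had a count in any library and 14994 were tested. Total counts were 21375211, 28143957 and 40334577 in the WT libraries, 37405163, 21119037 and 18067377 in the Usp21 KO libraries and 31292870, 19571130 and 32458047 in the dKO libraries. Levels below are counts scaled to library size (CPM) as mean ± SD over n = 3 libraries, and log2 fold changes are given ± SE from edgeR's quasi-likelihood test, whose p-values carry Benjamini-Hochberg adjustment. The 13 genes encoded by mitochondrial DNA were listed at 0 in every library, so that list could not be tested.

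Both targeted genes were lower in the groups labelled as lacking them, and Foxp3 was lower in the dKO. Usp21 (ENSMUSG00000053483, mm10 chromosome 1, 171281945 to 171287991) stood at 63.3 ± 2.72 CPM in WT, 25.4 ± 2.49 in Usp21 KO and 27.9 ± 1.59 in dKO, or 40.1% and 44.1% of WT. Usp22 (ENSMUSG00000042506, chromosome 11, 61151785 to 61175055) stood at 71.1 ± 1.74 CPM in WT, 73.8 ± 8.64 in Usp21 KO and 25.4 ± 3.58 in dKO, 35.7% of WT. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) stood at 660 ± 34.2 CPM in WT, 730.0 ± 85.3 in Usp21 KO and 333 ± 36.6 in dKO, 50.5% of WT. No library of a group labelled as lacking a gene overlapped the WT libraries in that gene. Gene-level counts include reads from exons that a deletion may have left in place.

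**Figure D1:**
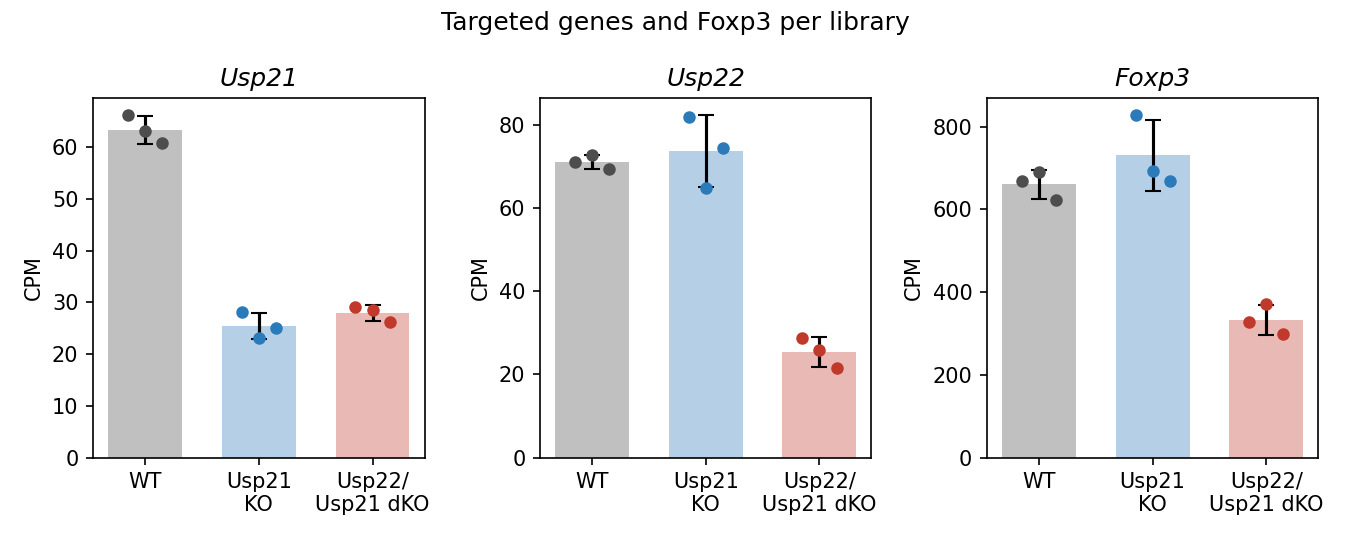
CPM of Usp21, Usp22 and Foxp3 (vertical axes) by genotype, with bars for the mean, error bars for the SD and points for the 3 libraries of each group. Foxp3 averaged 333 CPM in dKO and 660 CPM in WT.

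The first comparison set Usp21 KO against WT. Usp21 itself fell (log2 fold change -1.31 ± 0.09, adjusted p = 0.000371). The unnamed gene model 5830416I19Rik (ENSMUSG00000106219, chromosome 5, 64044978 to 64050228) rose from 0.166 ± 0.106 CPM in WT to 6.31 ± 2.03 CPM in Usp21 KO (log2 fold change 5.31 ± 0.46, adjusted p = 0.00217), and stood at 2.64 ± 0.317 CPM in dKO. These 2 were the genes that passed among 14994, and 1596 genes had an unadjusted p under 0.05. The next smallest p-values, none of which passed, belonged to Cd160, an immunoglobulin-family receptor, at -0.66 ± 0.10, to Rab4a, a small GTPase of endosomal recycling, at -1.96 ± 0.29, and to the gene model Gm12070 at 4.05 ± 0.65 (adjusted p = 0.197 for each). Foxp3 (0.15 ± 0.10, adjusted p = 0.632) and Usp22 (0.05 ± 0.11, adjusted p = 0.889) did not pass. Without Usp21 KO replicate 2 the edgeR test passed 17 genes, and without Usp21 KO replicate 3 it passed 4. With no filter on low counts it passed 40, and DESeq2 passed 193.

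None of the 754 measured list members passed in this comparison by edgeR or limma voom, while 172 had an unadjusted p under 0.05 and DESeq2 passed 38. As whole lists, 5 were called higher and 9 lower by limma's camera test with its preset correlation, and 0 of the 14 held with an estimated correlation. The cell cycle list had a median log2 fold change of 0.81, with 0 of 40 members past the threshold over all genes tested and 25 higher when adjusted over the list alone (camera adjusted p = 1.1e-28, adjusted p = 0.438 with an estimated correlation). Its median was 0.44 without Usp21 KO replicate 2, whose cell cycle score was 0.55 against -0.29 and -0.18 in the others of its group. Among its members, the kinetochore gene Cenpf stood at 11.3 ± 3.71 CPM in Usp21 KO and 5.07 ± 0.688 in WT, and the checkpoint kinase gene Bub1b at 23.7 ± 6.62 and 11.4 ± 1.90 (adjusted p = 0.204 for both). The list of cytosolic ribosomal proteins had a median of -0.32, with 0 of 76 members past the threshold and 43 lower when adjusted over the list alone (camera adjusted p = 2.88e-29, adjusted p = 0.438 with an estimated correlation). Rpl37a stood at 75.6 ± 3.58 CPM against 108 ± 8.88 in WT, and Rpl39 at 68.6 ± 3.62 against 94.3 ± 5.68 (adjusted p = 0.204 for both). The oxidative phosphorylation list had a median of -0.16, with 0 of 75 members past the threshold and 5 lower over the list alone (camera adjusted p = 3.91e-15, adjusted p = 0.472 with an estimated correlation). Its members with the smallest p-values, Uqcrh at -0.38 ± 0.07 and Uqcrc2 at -0.28 ± 0.06, both encode subunits of respiratory complex III.

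Usp21 KO replicate 2 stood apart from its group in T cell state. List scores are mean log2 deviations from the average of the 9 libraries. Its score for effector Treg genes was 0.95 against -0.19 and -0.22 in the other Usp21 KO libraries. Its score for naive or resting T cell genes was -0.97 against 0.07 and 0.16. Itgae, an integrin subunit of tissue Treg cells, stood at 366 CPM in that library against 170.0 and 137 CPM in its group. The effector Treg list was called higher (median 0.39, camera adjusted p = 0.00174) and the naive list lower (median -0.26, camera adjusted p = 1.63e-05), but with an estimated correlation the adjusted p was 0.721 and 0.583. Without Usp21 KO replicate 2 the effector list had a median of 0.01 and an adjusted p of 0.3, with camera's direction reversed. The naive list then had a median of -0.03 and an adjusted p of 0.119. No member of either list passed by edgeR, DESeq2 or limma voom (4 effector Treg and 0 naive genes at an unadjusted p under 0.05).

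None of the remaining lists called against WT in this comparison held with an estimated correlation. Glycolysis (median 0.12, camera adjusted p = 0.0133, 0.583 estimated), plasma cell markers (0.66, 0.00599, 0.721 estimated) and erythroid and platelet markers (0.77, 0.000459, 0.583 estimated) were higher. Cholesterol synthesis (-0.14, 0.00599, 0.472 estimated), the type I interferon response (-0.04, 0.0128, 0.696 estimated), the heat shock list (-0.13, 0.00599, 0.583 estimated), the immediate early list (-0.31, 0.00893, 0.721 estimated), CD8 T and NK cell markers (-0.26, 0.0416, 0.721 estimated) and conventional CD4 T cell markers (-0.18, 0.0269, 0.438 estimated) were lower. Each of these calls was lost without some single library. Without Usp21 KO replicate 2 the adjusted p was 0.339 for erythroid and platelet markers, 0.153 for glycolysis, 0.0881 for plasma cell markers, 0.403 for the immediate early list and 0.0676 for conventional CD4 T cell markers. With Usp21 KO replicate 3 left out it was 0.563 for plasma cell markers, 0.161 for the immediate early list, 0.0777 for interferon, 0.164 for heat shock, 0.059 for cholesterol synthesis and 0.059 for CD8 T and NK cell markers. With Usp21 KO replicate 1 left out it was 0.0512 for conventional CD4 T cell and 0.755 for CD8 T and NK cell markers. Without WT replicate 2 it was 0.0707 for glycolysis, 0.102 for plasma cell markers, 0.361 for the immediate early list, 0.15 for interferon and 0.0632 for heat shock. Without WT replicate 3 it was 0.054 for cholesterol synthesis, 0.0885 for conventional CD4 T cell and 0.454 for CD8 T and NK cell markers, and without WT replicate 1 it was 0.167 for the last. Treg identity, the T helper, hypoxia, amino acid, NF-kB, TGF-beta and IL-2 lists, the SAGA complex, other deubiquitinases, p53 and apoptosis, homing receptors, and B cell and myeloid markers were not called. The 4 measured sex-linked genes held 0 that passed, with 0 also by DESeq2, by limma voom and at an unadjusted p under 0.05.

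The second comparison set the dKO against WT. Foxp3 fell (log2 fold change -0.99 ± 0.10, adjusted p = 0.00141) together with Usp22 (-1.49 ± 0.11, adjusted p = 0.000213) and Usp21 (-1.18 ± 0.09, adjusted p = 0.000197). Of the cell cycle genes 31 of 40 rose, and of the ribosomal protein genes 27 of 76 fell. Of the myeloid, the CD8 T and NK, and the erythroid markers 3 of 32, 3 of 23 and 2 of 13 rose. With an estimated correlation none of these 5 lists was called (adjusted p = 0.29, 0.347, 0.519, 0.347 and 0.432). In all, 866 of 14994 genes passed, 451 higher and 415 lower, and 3363 had an unadjusted p under 0.05. Of these 866, 325 differed by more than 2-fold, 238 higher and 87 lower. The 6 libraries of this comparison alone gave 2315, and DESeq2 1499. With library totals as the only scaling, 807 were higher and 236 lower, so that the higher share was 77.4% in place of 52.1%. No dKO library overlapped a WT library in any of the 866 genes. Chance gives that arrangement in 10% of unselected genes, but genes selected by this test nearly always show it, so it adds no support.

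The rise with the smallest p was that of Col6a4, a collagen VI chain, from 0.372 ± 0.0370 CPM in WT to 9.01 ± 0.774 CPM in dKO (log2 fold change 4.57 ± 0.25, adjusted p = 5.18e-05). Epas1, the hypoxia-inducible factor HIF-2 alpha, rose from 10.9 ± 0.696 to 55.2 ± 6.21 CPM (2.35 ± 0.16, adjusted p = 0.000113). Ltf (4.05) and Ngp (3.95), which encode proteins of neutrophil granules, Gzma (2.40), a granzyme of cytotoxic lymphocytes, and Pdlim4 (2.35) rose too. Further rises were in Depdc1b (2.31), Neil3 (2.24), Nek2 (2.23) and Troap (2.21), and of these Nek2 encodes a mitotic kinase and Troap a spindle protein. Among the falls, Pianp went from 81.6 ± 3.66 CPM in WT to 0.238 ± 0.105 CPM in dKO (-8.32 ± 1.18, adjusted p = 0.0116), with 36.4, 2.82 and 43.3 CPM in the Usp21 KO libraries. Cdcp1 (-2.77), Wdr66 (-2.10), Prss12 (-2.04), Abhd14b (-1.93), Chil5 (-1.87), Aldh1l1 (-1.78), Ksr2 (-1.77), Catsperd (-1.75) and the histone deacetylase gene Hdac9 (-1.74) fell too. Col6a4, Epas1, Troap, Cdcp1, Wdr66, Abhd14b, Chil5 and Catsperd passed whichever 1 of the 6 libraries was left out, whereas Ltf, Ngp, Prss12 and Ksr2 passed in none of those 6 fits. Pianp was lost without any 1 of the dKO libraries, and the other genes of this paragraph passed in some of the fits.

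Treg identity genes fell in part. Of 32 measured, 4 fell and 28 did not pass, and 4 fell when adjusted over the list alone (median -0.16, camera adjusted p = 0.00139, adjusted p = 0.29 with an estimated correlation). Those that fell were Foxp3, the semaphorin receptor gene Nrp1 (-0.44), Tnfrsf18, which encodes GITR (-0.56), and Tnfrsf4, which encodes OX40 (-0.54). Foxp3 passed under every alternative tried, and the other 3 did not pass with library totals or with the score of other cell types as a covariate, where they stood at -0.47, -0.75 and -0.68. Il2ra, the interleukin-2 receptor alpha chain, at 609 ± 33.0 CPM in dKO and 696 ± 44.9 in WT, and Ctla4, at 304 ± 39.0 and 324 ± 51.0, did not pass (adjusted p = 0.214 and 0.699). With 1 library left out, 2 members fell without WT replicate 3 and 1 without WT replicate 1 or 2 or dKO replicate 1, 2 or 3, Foxp3 in each fit. Up to 1 member rose in these fits. Of the IL-2 and STAT5 list, 2 of 24 fell, here and adjusted over the list alone, the transcription factor gene Stat5b (-0.46) and Tnfrsf18 (camera adjusted p = 0.00352, adjusted p = 0.347 with an estimated correlation). Of the NF-kB list, 2 of 30 fell, 4 when adjusted over the list alone, the cytokine gene Ltb (-0.48) and the A20-binding Tnip1 (-0.39; camera adjusted p = 0.000163, adjusted p = 0.519 with an estimated correlation), and 0 did so in any fit without 1 library. Of the T helper list, 2 of 20 rose, 6 when adjusted over the list alone, and both did so without any 1 library: the follicular homing receptor gene Cxcr5 (0.94) and the cytokine gene Il4 (1.59; camera adjusted p = 0.0166, adjusted p = 0.519 with an estimated correlation). With the score of other cell types as a covariate neither passed, at log2 fold changes of 0.80 for Cxcr5 and 1.48 for Il4. None of the 30 effector Treg genes passed by edgeR or limma voom (6 at an unadjusted p under 0.05, 2 by DESeq2), and none of the 22 naive T cell genes by edgeR (3 unadjusted, 2 by DESeq2, 1 by limma voom).

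Most cell cycle genes rose. Of 40 measured, 31 rose and 0 fell, and 38 rose when adjusted over the list alone (median 1.53, camera adjusted p = 1.25e-45, adjusted p = 0.29 with an estimated correlation). Cenpf rose from 5.07 ± 0.688 CPM in WT to 23.5 ± 2.34 CPM in dKO (2.21 ± 0.22, adjusted p = 0.00118), and the spindle gene Nusap1 (1.93), the S-phase transcription factor gene E2f1 (1.51) and Bub1b (1.57) rose too. The number that rose was 7, 12 and 23 without WT replicate 1, 2 or 3 and 12, 14 and 10 without dKO replicate 1, 2 or 3. The score of markers of other cell types, the mean of the B cell, myeloid, CD8 T and NK, and erythroid and platelet scores, was also higher in the dKO libraries (0.69, 0.56 and 0.86) than in the WT libraries (-0.04, -1.19 and 0.03). With that score as a covariate, 2 of the 40 members rose with a median of 0.89, and 93 genes in all passed in place of 866, of which 37 were higher and 56 lower. The score separates the groups, so the covariate also takes up part of the genotype difference. Calls lost with it, here and below, therefore do not show that other cell types account for them.

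Many genes of cytosolic ribosomal proteins fell. Of 76 measured, 27 fell and 0 rose, and 47 fell when adjusted over the list alone (median -0.43, camera adjusted p = 1.88e-24, adjusted p = 0.347 with an estimated correlation). Rpl29 fell from 37.3 ± 1.25 to 15.4 ± 0.685 CPM (-1.27 ± 0.08, adjusted p = 9.85e-05), and Rps19 (-0.79), Rpl37a (-0.62) and Rpl18 (-0.50) fell too. Rpl29 (chromosome 9, 106429454 to 106431568) lies close to Abhd14a (start 106440051, -0.93) and Abhd14b (start 106447459, -1.93), which also fell. Whether its larger fall is local to this stretch or belongs to the family was not tested. The number that fell was 3, 5 and 8 without WT replicate 1, 2 or 3, 10, 5 and 4 without dKO replicate 1, 2 or 3, and 1 with the score of other cell types as a covariate. The median stayed between -0.48 and -0.39 without any 1 library and was -0.27 with the covariate, and across all alternatives tried Rpl29 stayed between -1.31 and -1.17, Rps19 between -0.85 and -0.60, Rpl37a between -0.69 and -0.53 and Rpl18 between -0.55 and -0.40. Reads that also match the many near-identical processed pseudogenes of these genes may have been left out of the counts or assigned to those pseudogenes. Single values of this family are therefore uncertain.

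Other lists held few members that passed. In metabolism, Uqcrh fell in oxidative phosphorylation (1 of 75, 0 over the list alone), Aldoc and the glucose transporter gene Slc2a3 fell in glycolysis (2 of 19, 2 over the list alone), and in the hypoxia list Egln3 rose and P4ha1 fell (2 of 19, 2 over the list alone). Psat1 of serine synthesis rose in the amino acid list (1 of 19, 3 over the list alone), and Srebf2 was among those that fell in cholesterol synthesis (3 of 20, 6 over the list alone; camera adjusted p = 0.0233, adjusted p = 0.488 with an estimated correlation, 0.0842 without WT replicate 3 and 0.103 without dKO replicate 1). In the SAGA complex Usp22 fell and Taf9b rose (2 of 25, 2 over the list alone), Usp3 (-0.57) fell among 50 other deubiquitinases (1 over the list alone), and Hspa8 fell among 25 heat shock genes (0 over the list alone). Of 29 p53 and apoptosis genes 3 rose and 3 fell, 4 and 4 over the list alone, among them Bid (-0.47), Sesn1 (-0.58) and Mcl1 (-0.52). Of 30 homing receptor genes Cxcr5, the gut homing receptor gene Ccr9 (1.00) and Itgal (0.27) rose and Selplg (-0.36) fell, 3 and 2 over the list alone. Oas3 alone rose among 39 interferon genes, with 0 over the list alone. None of 24 TGF-beta genes passed by edgeR, DESeq2 or limma voom (4 unadjusted), and none of 26 immediate early genes by edgeR (median -0.53, camera adjusted p = 0.00844, adjusted p = 0.822 with an estimated correlation, 0.552 without WT replicate 2; 3 unadjusted, 1 by DESeq2, 0 by limma voom). With the score of other cell types as a covariate Psat1 passed, and Ccr9, P4ha1, Bid and Sesn1 did not, at log2 fold changes of 0.95, -0.82, -0.43 and -0.49. Without any 1 library, Cxcr5, Ccr9, Psat1, P4ha1, Bid and Sesn1 passed, and the other genes of this paragraph apart from Usp22 were lost in at least 1 such fit.

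Some markers of other spleen cells rose in dKO. Of 32 myeloid markers 3 rose, Cebpa (1.11), Camp (3.73) and Ngp, 6 when adjusted over the list alone (median 1.33, camera adjusted p = 9.49e-07, adjusted p = 0.519 with an estimated correlation), and 1 rose in each fit without 1 library. Of 23 CD8 T and NK cell markers 3 rose, Klrb1c (1.35), Gzma and Klrk1 (1.71), 11 over the list alone (median 1.37, camera adjusted p = 1.64e-06, adjusted p = 0.347 with an estimated correlation), with 0 higher without dKO replicate 2 or 3, 1 without WT replicate 1 or 2, and 2 without WT replicate 3 or dKO replicate 1. Of 13 erythroid and platelet markers Hba-a2 (1.08) and Alas2 (1.57) rose, 5 over the list alone (camera adjusted p = 8.62e-06, adjusted p = 0.432 with an estimated correlation), with 3 higher without dKO replicate 1 and 0 without any other library. With the replicate number as a block, Camp, Ngp, Gzma, Klrk1 and Alas2 did not pass. Of 24 B cell and 15 plasma cell markers none passed by edgeR, with 2 and 6 at an unadjusted p under 0.05, 1 and 1 by DESeq2 and 1 and 0 by limma voom. Their medians were 0.45 and 1.20 (camera adjusted p = 0.0124 and 0.00111, with an estimated correlation adjusted p = 0.814 and 0.519), and the B cell call was lost without WT replicate 2 (adjusted p = 0.427). Of 15 markers of conventional CD4 T cells Ccr9 and Cd40lg (0.44) rose and Cd6 (-0.32) fell, 3 and 1 over the list alone. With 1 library left out, Ccr9 passed in 6 of 6 fits, Cd40lg in 1 and Cd6 in 0. Of 12 markers abundant in such cells, picked after the lists were seen, 11 had higher and 1 a lower mean in dKO. Some of the 12 were low in these libraries, and none of those named next passed. Lyz2 stood at 430.0 ± 207 CPM in dKO and 101 ± 72.3 in WT, Igkc at 494 ± 89.3 and 141 ± 77.5, Cd74 at 142 ± 5.16 and 128 ± 35.8, Cst3 at 67.2 ± 9.06 and 62.4 ± 10.02, and Ccl5 at 17.7 ± 1.22 and 24.1 ± 3.20 (adjusted p = 0.229, 0.18, 0.906, 0.811 and 0.67). Of the 4 measured sex-linked genes none passed by any of the 3 tools (1 unadjusted).

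**Figure D2:**
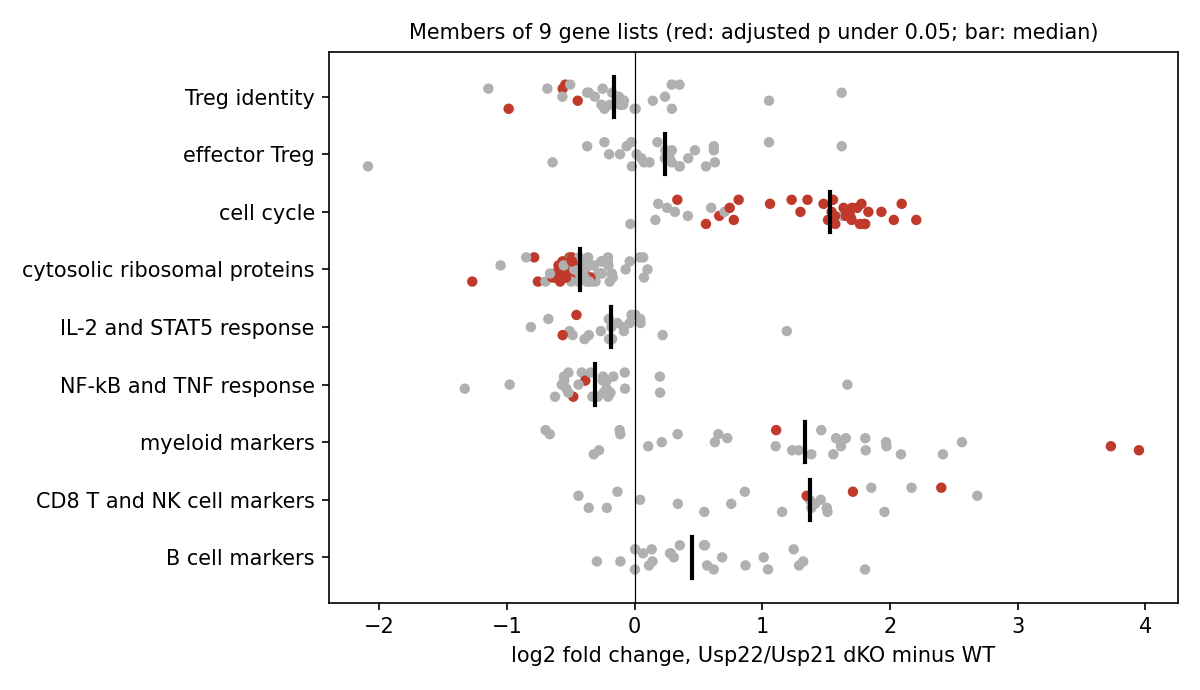
Log2 fold change of dKO minus WT (horizontal axis) for the measured members of 9 gene lists (vertical axis), in red for adjusted p under 0.05, with a bar at each list's median. Cell cycle genes have a median of 1.53 and cytosolic ribosomal protein genes a median of -0.43.

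**Figure D3:**
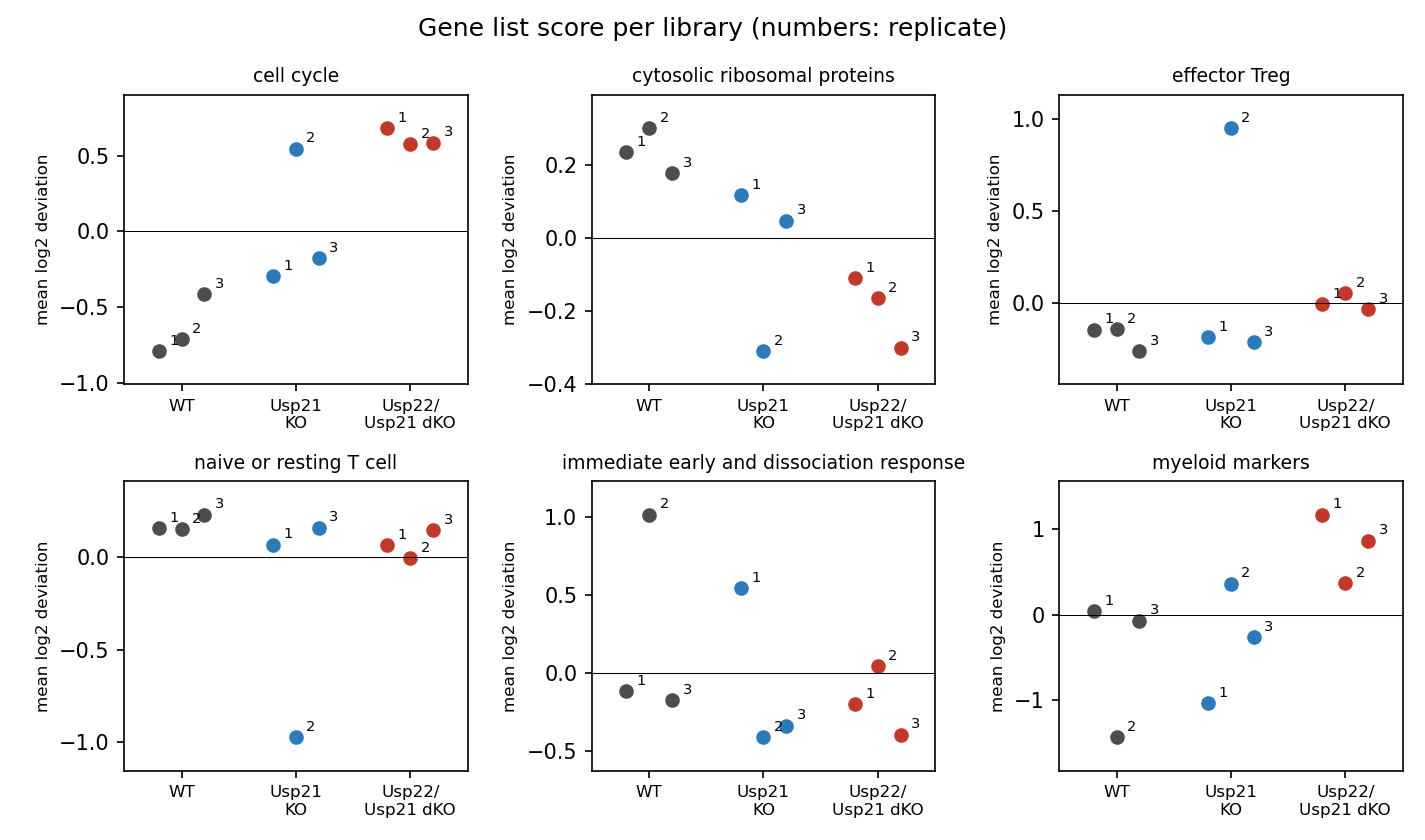
Score of 6 gene lists per library, as mean log2 deviation from the average of the 9 libraries (vertical axes), by genotype, with the replicate number at each point. The dKO libraries lie between 0.57 and 0.68 in the cell cycle score, WT libraries between -0.79 and -0.41, and Usp21 KO replicate 2 stands at 0.95 in the effector Treg score.

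The number of genes that passed between dKO and WT was 193, 315 and 379 without WT replicate 1, 2 or 3 and 337, 283 and 255 without dKO replicate 1, 2 or 3, with 55.2% to 58.3% of them higher. Immediate early genes, which respond to handling, scored highest in WT replicate 2 (1.02), Usp21 KO replicate 1 (0.55) and, within its group, dKO replicate 2 (0.05), and without these 3 libraries 147 genes passed, 115 higher and 32 lower.

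The third comparison set the dKO against Usp21 KO, which differ by design in Usp22. Foxp3 fell (-1.13 ± 0.10, adjusted p = 0.000543) and so did Usp22 (-1.54 ± 0.11, adjusted p = 0.000152), while Usp21 did not pass (0.13 ± 0.09, adjusted p = 0.4). Of the NF-kB, STAT5 and Treg identity genes 5 of 30, 4 of 24 and 4 of 32 fell, and 5 of 23 CD8 T and NK cell markers rose. With an estimated correlation none of these 4 lists was called (adjusted p = 0.552, 0.216, 0.211 and 0.216). In all, 735 genes passed, 255 higher and 480 lower, with 3542 at an unadjusted p under 0.05 and 208 beyond 2-fold (96 higher, 112 lower). The 6 libraries of this comparison alone gave 147, and DESeq2 1591. With library totals as the only scaling, 654 were higher and 281 lower, a higher share of 69.9% in place of 34.7%. In none of the 735 genes did the groups overlap, which chance gives in 10% of unselected genes. Selection by the test nearly requires it, so it adds no support.

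Col6a4 rose from 0.385 ± 0.112 to 9.01 ± 0.774 CPM (4.56 ± 0.26, adjusted p = 6.25e-05) and Epas1 from 11.1 ± 2.74 to 55.2 ± 6.21 CPM (2.31 ± 0.16, adjusted p = 0.000138). Spag16 (2.25), Ggt5 (2.10), the NK receptor genes Klrk1 (2.03) and Klrb1c (2.02), Gzma (1.95), Ldlrad3 (1.91), the integrin gene Itgam (1.87) and Ampd1 (1.85) rose too. Pianp (-6.75), the scavenger receptor gene Stab1 (-4.07), Cdcp1 (-3.29), Dscam (-3.15), Chmp4c (-2.83), Utf1 (-2.81), Prss12 (-2.70), the Notch ligand gene Jag1 (-2.50), Cpe (-2.49) and Nrn1 (-2.47) fell. Among these, Stab1 stood at 10.6 CPM in Usp21 KO replicate 2 against 2.77 and 2.82 CPM in the others of its group, Dscam at 40.9 against 16.1 and 11.9 CPM, and Nrn1 at 95.3 against 29.5 and 27.4 CPM. Foxp3, Usp22, Col6a4, Epas1, Spag16, Ggt5, Klrb1c, Ampd1 and Cdcp1 passed whichever 1 library was left out, and the other named genes of this paragraph in some of the 6 fits.

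Of 32 Treg identity genes, 4 fell, namely Foxp3, Nrp1 (-0.50), Socs2 (-0.77) and Tnfrsf4 (-0.59), and adjusted over the list alone 10 fell and 1 rose (camera adjusted p = 0.00022, adjusted p = 0.211 with an estimated correlation). Of 30 NF-kB genes, 5 fell, 15 over the list alone, among them Ltb (-0.65), the NF-kB subunit gene Rela (-0.36), Tnip1 (-0.54) and Traf1 (-0.61; camera adjusted p = 1.72e-07, adjusted p = 0.552 with an estimated correlation). Of 24 IL-2 and STAT5 genes, 4 fell, 9 over the list alone: Stat5b (-0.52), Stat5a (-0.27), Socs2 and Osm (-0.46; camera adjusted p = 0.000218, adjusted p = 0.216 with an estimated correlation). Without Usp21 KO replicate 2, the numbers that fell were 13, 12 and 10 in these 3 lists, with 3 Treg identity genes higher, and across the other fits without 1 library they were 1 to 6, 0 to 11 and 1 to 5. Of 40 cell cycle genes Cenpf (1.06) and E2f1 (0.82) rose, 5 over the list alone (camera adjusted p = 5.86e-11, adjusted p = 0.663 with an estimated correlation), and 33 rose without Usp21 KO replicate 2 and at most 1 without any other library. Of 76 cytosolic ribosomal protein genes Rpl13a (0.36) rose and Rpl29 (-0.98) fell, with 1 lower and 0 higher over the list alone (camera adjusted p = 0.0234, adjusted p = 0.889 with an estimated correlation), and 18 fell without Usp21 KO replicate 2. That call was lost without Usp21 KO replicate 1 (adjusted p = 0.573), Usp21 KO replicate 3 (0.436) or dKO replicate 3 (0.318). Of 75 oxidative phosphorylation genes 4 rose, 7 over the list alone, among them Uqcr10 (0.36) and Uqcrc2 (0.27; camera adjusted p = 7.02e-05, adjusted p = 0.687 with an estimated correlation), with 12 higher without Usp21 KO replicate 2 and 0 without any other library.

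Of 23 CD8 T and NK cell markers 5 rose, 10 over the list alone, among them Klrb1c, Xcl1 (1.67), Klrc1 (2.59) and Klrk1 (camera adjusted p = 1.67e-10, adjusted p = 0.216 with an estimated correlation), with 11 higher without Usp21 KO replicate 2 and 1 to 3 without any other library. Itgam rose among 32 myeloid markers (1 over the list alone; camera adjusted p = 2.69e-06, adjusted p = 0.687 with an estimated correlation), and the B cell transcription factor gene Pax5 (1.39) among 24 B cell markers (1 over the list alone; camera adjusted p = 0.000495, adjusted p = 0.687 with an estimated correlation, 0.0501 without Usp21 KO replicate 1). In the fit without Usp21 KO replicate 2, 7 myeloid and 3 B cell markers rose. Of 15 conventional CD4 T cell markers Ccr9 (1.61) and Cd40lg (0.47) rose and Cd6 (-0.47) fell, with 2 higher and 1 lower over the list alone (camera adjusted p = 0.00528, adjusted p = 0.211 with an estimated correlation). The estimate for this list was -0.005, below the preset, so correlation does not account for the higher p. Cxcr5 (0.87) and Il4 (1.60) rose in the T helper list (2 of 20; 3 higher and 1 lower over the list alone), and Psat1 (0.59) and Mthfd2 (0.78) in the amino acid list (2 of 19; 3 higher and 2 lower over the list alone). Of 29 p53 and apoptosis genes 3 rose and 3 fell, among them Fasl (1.36), Sesn1 (-0.58), Bbc3 (-0.45) and Trp53 (-0.36), with 3 and 4 over the list alone. Of 30 homing receptor genes 2 rose and 2 fell, 4 and 7 over the list alone, among them S1pr4 (-0.42) and Selplg (-0.39). Slc2a3 (-0.62) and Aldoc (-0.78) fell in glycolysis (2 of 19, 2 over the list alone), P4ha1 (-0.57) and Ndrg1 (-0.53) in the hypoxia list (2 of 19, 3 over the list alone) and Srebf2 (-0.30) in cholesterol synthesis (1 of 20; 1 higher and 2 lower over the list alone). Psmd14 (0.26) and Usp14 (0.31) rose among 50 other deubiquitinases (1 over the list alone), and Usp22 fell as 1 of 25 SAGA genes (1 over the list alone). Isg20 (0.36) and Trim30a (0.31) rose and Igtp (-0.26) fell in the interferon list (3 of 39; 2 higher and 2 lower over the list alone). Klrb1c, Ccr9, Cd6, Cxcr5, Il4, Psat1, Mthfd2, Sesn1 and Usp22 passed whichever 1 library was left out. The other genes named so far in this paragraph were lost in at least 1 such fit. Psmd14, Usp14, Isg20, Trim30a, Igtp, Trp53 and Srebf2 passed in 1 of the 6 fits. By edgeR no member passed of the effector Treg, naive, TGF-beta, heat shock, immediate early, plasma cell, erythroid and sex-linked lists, with 0 also over each list alone save 1 higher and 1 lower TGF-beta gene. In that order they held 7, 3, 3, 3, 1, 2, 0 and 1 members at an unadjusted p under 0.05, 3, 1, 3, 1, 1, 1, 0 and 0 by DESeq2, and 1 TGF-beta gene by limma voom. With 1 library left out, the most that rose in any fit were 9, 2, 2, 6, 0, 1, 2 and 0. The most that fell were 2, 6, 3, 0, 1, 1, 0 and 0. Without Usp21 KO replicate 2 the effector Treg list was called higher (camera adjusted p = 0.00614), the reverse of its direction with all libraries.

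The number of genes that passed between dKO and Usp21 KO was 287, 2192 and 734 without Usp21 KO replicate 1, 2 or 3 and 190, 192 and 168 without dKO replicate 1, 2 or 3. With the score of other cell types as a covariate 386 genes passed, 113 higher and 273 lower.

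Both dKO comparisons share the dKO libraries. Of the genes that passed, 129 were higher and 240 lower in both, and 0 went in opposite directions. Independent lists of these sizes would share 7.67 and 13.3 genes, and in 20 simulations of unchanged groups against the shared libraries at most 1 gene was shared. Almost no gene passes in such simulations, so a shared count near 0 was close to fixed in advance. Neither reference suits long lists that share the dKO libraries, so the size of the overlap was not tested. The log2 fold changes of the 14994 genes correlated across genes at 0.679 (simulated 0.49), with a covariance of 0.262 (simulated 0.0657). Genes are not independent replicates, and 3 shared libraries were too few to be divided between the comparisons. Part of the excess may therefore come from the shared libraries. Usp21 KO against WT and dKO against WT shared both genes of the first, 5830416I19Rik higher and Usp21 lower, where independent lists would share 0.03 each. The correlation across genes was 0.497 (simulated 0.501), with a covariance of 0.162 (simulated 0.0676).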

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

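The fits without the 3 libraries highest in immediate early genes and with either score as a covariate were chosen after the results were seen, and the other alternatives before the data were examined. Where no reason is given, the cause of a change was not tested. Values run Usp21 KO against WT, dKO against WT and dKO against Usp21 KO. Median-ratio size factors gave 2, 854 and 708 genes, a CPM of at least 1 in 3 libraries 2, 885 and 806, and limma voom 2, 945 and 864, all within 1.5 times the reported 2, 866 and 735. Library totals put the median of all genes at 0.09 and 0.087 in the dKO comparisons, in place of -0.009 and -0.007, and gave 807 higher and 236 lower in dKO against WT and 654 and 281 in dKO against Usp21 KO. Without a filter, Usp21 KO against WT had 40 genes, 21 higher and 19 lower. The fold threshold, stricter by construction, left 82 (59 and 23) and 31 (15 and 16) in the dKO comparisons. The 6 libraries alone gave 1 (0 higher), 2315 (1232 and 1083) and 147 (55 and 92), and DESeq2 193 (125 and 68), 1499 (816 and 683) and 1591 (649 and 942). Of 9 same-numbered pairs 4 correlated above 0.1 in their deviations (-0.268 to 0.259), so the numbers did not pair all 3 groups. The 3 WT and dKO pairs lay at 0.118 to 0.259 and their 6 differently numbered pairs at -0.193 to 0.101, a hint of pairing from the data for these groups. The replicate block gave 2, 606 (327 and 279) and 461 (153 and 308) genes, and in dKO against WT the markers Camp, Ngp, Gzma, Klrk1 and Alas2 did not pass with it. Leaving out 1 library, with fewer samples by construction, gave 2 to 17 genes (1 to 6 higher, 1 to 11 lower), 193 to 379 (107 to 221, 86 to 158) and 168 to 2192 (60 to 1056, 108 to 1136), with 17 and 2192 without Usp21 KO replicate 2. Without the 3 libraries, 3 genes (2 higher), 147 (115 and 32) and 114 (80 and 34) passed. With the immediate early covariate 4 (3 higher), 656 and 1314 (569 and 745) passed, and with the other cell types covariate 7 (4 and 3), 93 (37 and 56) and 386 (113 and 273). Of the genes named that passed, 2 of 2, 28 of 67 and 18 of 66 did so without any 1 library, and 1, 10 and 7 under every alternative tried, and none that passed changed direction. Usp22 in Usp21 KO against WT, which never passed, changed sign between -0.031 and 0.132 with 1 library left out and at -0.013 without the 3 libraries. Of the lists called by camera, 14, 13 and 10, none was called with an estimated correlation (0, 0 and 0), fry called 0, 6 and 5, 7 to 14 were called in Usp21 KO against WT with 1 library left out, and 8 in dKO against WT with the other cell types covariate. Lists that changed direction in Usp21 KO against WT with 1 library left out were the immediate early list (adjusted p 7.51e-07 to 0.403), myeloid markers (0.0154 to 0.684) and effector Treg (4.73e-07 to 0.3), and in dKO against Usp21 KO effector Treg (0.00614 to 0.633). With the immediate early covariate the immediate early list (0.701) and myeloid markers (0.00172) did so in Usp21 KO against WT. With the other cell types covariate, which is built from the B cell, myeloid, CD8 T and NK, and erythroid lists, the immediate early list (1.09e-09), B cell markers (0.000162) and plasma cell markers (0.84) did so in dKO against WT, and the immediate early (2.64e-16), homing (0.0397), ribosomal (0.0749), B cell (0.0482), plasma cell (0.0233) and myeloid (0.851) lists in dKO against Usp21 KO. At an adjusted p under 0.10 both dKO comparisons shared 343 higher and 458 lower genes. Depth was not varied.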

Other observations

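The tests below on fewer Treg cells, scaling, a single lower share of T cells, low values in single libraries and chance placement along the genome were chosen after the results were seen, as was the look at the Gimap genes. The Gimap genes, which lie side by side on chromosome 6 (48647234 to 48770851), comprised 8 measured genes for GTPases of lymphocyte survival and the antisense transcript Gimap1os, which overlaps Gimap1 in counts whose strand option is not recorded. In dKO against WT 7 of the 8 were lower and Gimap7 and Gimap1os did not pass (adjusted p = 0.0698 and 0.543, edgeR). The 9 genes had a median log2 fold change of -0.59, and of -0.59 and -0.49 with median-ratio size factors and library totals. Gimap3 fell from 1752 to 860 CPM (-1.03, adjusted p = 0.00267, edgeR), Gimap6 from 851 to 424 CPM (-1.01, adjusted p = 0.00141), Gimap4 from 940 to 553 CPM (-0.77, adjusted p = 0.00492) and Gimap8 from 546 to 361 CPM (-0.59, adjusted p = 0.00389), and 6 or 7 members fell whichever 1 library was left out. With the score of other cell types as a covariate 1 member fell. Against Usp21 KO 5 of the 9 were lower, and in Usp21 KO against WT none passed by edgeR, DESeq2 or limma voom (4 at an unadjusted p under 0.05). Of 9 Mcm genes of the replication helicase, 4 were higher in dKO against WT. The T cell surface gene Cd5 stood at 615 ± 20.1 CPM in dKO and at 952, 923 and 896 CPM in the WT libraries.

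Foxp3 was lower in dKO. The tables argue against 3 technical accounts of the fall of 0.99 on the log2 scale as its whole cause. Fewer Treg cells in the sorted dKO samples would lower the other Treg identity genes alike, but their median was -0.144 (95% bootstrap interval -0.26 to -0.09). RNA of non-T cells would lower pan T cell genes alike, but the median of 17 was -0.245 (-0.342 to -0.077). Several of the 17 did pass as lower, namely Cd5 (-0.586), Cd2 (-0.485), Cd3g (-0.412), Cd3d (-0.404), Skap1 (-0.342) and Cd6 (-0.32). None passed as higher and none fell as far as Foxp3, so dilution as a part of the cause stays open. Both intervals resample genes and not libraries, so they hold no spread between mice. Listed Treg identity genes that other cells in the sort also express would fall less, which weakens the argument against fewer Treg cells. Scaling between libraries would end the fall, which was -0.886 in the smaller case of the other 2 scalings. A lower Foxp3 transcript level in dKO Treg cells may account for it as a hypothesis, and whether Usp22 alone would do so stays open, since no group lacked Usp22 alone.

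Some markers of other cell types were higher in dKO, although the sort by the Foxp3 reporter should remove such cells. By limma on the library scores, dKO minus WT was 1.29 for myeloid (adjusted p = 0.0294), 1.31 for erythroid and platelet (0.0294), 1.06 for CD8 T and NK (0.0538) and 0.75 for B cell markers (0.139). The 4 intervals had the same width (0.277 to 2.296 for myeloid, -0.262 to 1.758 for B cell markers). This fit thus pooled the spread of 4 lists that vary together, as did that of the 6 differences below. The p-values of both do not rest on each list's own spread and may be too small. The score fits of this paragraph were unpaired, although same-numbered WT and dKO libraries gave a hint of pairing. A paired fit of the scores was not run. Low values in the 2 libraries highest in immediate early genes are argued against as the whole cause for myeloid and CD8 T and NK cell markers. Of these libraries only WT replicate 2 enters dKO minus WT. Without them and dKO replicate 2 the differences were 1.03 (95% interval 0.36 to 1.70, adjusted p = 0.0216) and 0.989 (0.49 to 1.49, 0.0145). That fit also dropped the lowest dKO library of both lists, which favours a difference, and no score fit dropped WT replicate 2 alone. With dKO replicate 2 kept, myeloid scores were 1.17, 0.37 and 0.86 in dKO against 0.04 and -0.07 in WT replicates 1 and 3. The CD8 T and NK scores were 0.81, 0.45 and 1.03 against -0.15 and 0.02. The account stays open for erythroid and platelet (0.938, -0.44 to 2.32, 0.19) and B cell markers (0.163, -0.27 to 0.60, 0.382). Whether a single lower share of T cells accounts for the pattern could not be decided. The largest of the 6 differences between the scores of the 4 lists, B cell minus erythroid and platelet markers, was -0.56 (95% interval -1.29 to 0.17, limma, adjusted p = 0.434). That interval is too wide to show that the lists rose alike. The third list mixes CD8 T and NK cell markers. Of its members that passed, Klrb1c and Klrk1 encode NK receptors and Gzma a granzyme of cytotoxic lymphocytes. Cd8a did not pass, at 1.90 CPM in dKO and 1.32 in WT (adjusted p = 0.436, edgeR). That list therefore does not count against this account. Of 12 transcripts abundant in such cells 11 had higher and 1 a lower mean in dKO, and none passed in edgeR (dKO and WT, among others: Lyz2 430 and 101 CPM, Igkc 494 and 141, Hbb-bs 53.8 and 23.4, Nkg7 28.4 and 22.5, Cd74 142 and 128, Cst3 67.2 and 62.4, Ccl5 17.7 and 24.1, S100a8 3.01 and 0.507). This decides little where WT levels are high, and some of the 12, such as S100a8, were low in these libraries. Expression of such genes by dKO Treg cells was not tested.

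Genes that passed in dKO against WT lay near each other on the chromosomes. Of 866, 162 had another among their 2 nearest tested neighbours, more than chance placement gave (mean 97.2, at most 146 in 10000 permutations within 20 classes of expression, p = 0.0001, the smallest these permutations can give). Neighbours of one family name (149 without them) and overlapping neighbours (136 without them) left the excess in place, and both numbers lay above the upper ends of their 95% permutation ranges, 117 and 106. DNA that flanks the targeted loci is argued against as the cause, since a call within 10 Mb of Usp21, Usp22 or Foxp3 had an odds ratio of 1.12 (95% interval 0.75 to 1.61, Fisher's exact test, two-sided p = 0.558). None of 527 windows along the genome held an excess of calls at adjusted p under 0.05 by a binomial test. The lowest was 0.0714, for 10 of 43 tested genes on chromosome 6 from 45000001. Such a scan does not test the origin of a segment. Regulation of neighbouring genes together may account for the clustering as a hypothesis. Other strain-derived segments of the genome were not tested and stay open, for the clustering and for single genes such as Col6a4, Pianp, Rab4a, 5830416I19Rik, Rpl29 and Abhd14b.

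With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In Usp21 KO against WT, 2 of the 10 splits gave at least the real 2 genes, and the highest other split gave 6. In dKO against WT, 1 split, the real one, gave 866 genes and the highest other split 0. In dKO against Usp21 KO, 1 split, the real one, gave 735 genes and the highest other split 0.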
